A study of Mus musculus with 2 samples.

How the data were processed

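Long-read RNA sequencing, in which one read spans most or all of a transcript, was analysed for left cerebral cortex of male mice. The mice were 14 days old and came from the B6CASTF1/J cross. The labels give 1 group with 2 biological replicates, each 1 library made from 2 µg of total RNA. Both samples carry the same donor identifier, and nothing beyond the labels says that they came from separate animals. The descriptions of the tissue samples carry different numbers, while the description of the library is the same for both and carries the number of replicate 1 only. Both kinds mention several males, so each sample may be a pool, and neither question is settled in the sources used here. The SD of a pool understates the spread between animals. The differences between the samples may therefore be technical, and the p-values of the tests on reads set them against counting error alone. Per the labels, ERCC spike-ins (Ambion mix 1) and Lexogen set 4 spike-ins (SIRVs) had been added.

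For each library the authors deposited a table of transcript models with the read count of each model, and the exon structure of the models. The values are whole-number counts with no normalization, and models with no read are not listed. Per the text deposited beside the tables, the models were built for each library alone on mm10 with the GENCODE M21 primary assembly annotation plus spike-in sequences. TALON is named in the deposited models as the source of unannotated features. The aligner and the software versions are not given in the sources used here. Each model has a deposited class. Known models match an annotated transcript, and incomplete splice matches (ISM) hold part of its chain of introns. NIC chains join annotated splice sites in an unannotated combination, and NNC chains hold at least 1 unannotated splice site. Genomic models overlap a gene without matching its splicing, antisense models lie opposite a gene, and intergenic models lie outside genes.

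Unannotated models were built for each library alone, so they were matched between libraries by chromosome, strand and chain of introns. Single-exon unannotated models cannot be matched this way and were pooled for each gene in the isoform test. Gene counts are sums of the reads of all models that the deposited table assigns to a gene, and CPM values scale them to all mouse reads of the library. Antisense reads are counted by the class of the model in the shares of classes and for antisense loci. In the comparison with ERCC reads they are counted by the class of the gene, which adds ISM, genomic, NIC and NNC models of antisense genes. Printed gene positions are 1-based, on mm10, from the GENCODE M21 annotation. All 55536 deposited mouse gene identifiers were found there, and 38923 (70.1%) had the same start and end. Mouse reads numbered 775048 in replicate 1 and 924222 in replicate 2.

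Shares of reads are given with 95% Wilson intervals, and log2 ratios with 95% intervals from the counts after adding 0.5 reads. These intervals and the floors of 3 counts cover counting error only. Per gene, the reads of the gene were set against all other mouse reads by a two-sided Fisher's exact test. The test took genes with at least 10 reads over both libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. It compares 2 libraries of 1 group, not conditions. A chi-square test of homogeneity was run over the same genes. Correlations across genes used log2(CPM + 1). Isoform usage was tested per gene by a chi-square test in genes with at least 50 reads in each library, with isoforms under 10 reads merged. For isoform diversity, an isoform counted when it held at least 10% of the gene's reads in both libraries, with ISM, genomic and antisense models left out. Percent spliced in was the share of reads with both junctions of an internal exon among these and the reads that join its neighbours directly. It was computed for exons with at least 20 such reads in each library. Exons that no read skipped in either library were left out, and unannotated exons were kept. Where an exon had several pairs of neighbours, the pair with most of these reads was used. Microexons were exons of 3 to 27 bp, and longer exons were those of 28 to 300 bp. Their medians were compared by a two-sided permutation test with 100000 draws.

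For 26 gene lists of cell types, neighbouring brain regions, activity, synapses, imprinting and splicing, the median log2 ratio of the tested members was set beside 10000 random lists of the same size. The random lists were matched on mean expression in 20 bins. A match on transcript length as well was added after the data were seen. The lists were excitatory, upper layer, deep layer and inhibitory neurons, astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus and ependyma, red blood cells, striatum, hippocampus, olfactory bulb, thalamus, immature neurons, proliferation, immediate early genes, synaptic vesicle, postsynaptic, GABA-A receptor, imprinted genes, splicing regulators and genes with known isoforms. Second lists for striatum, choroid plexus and meninges were added after the first lists had been seen, and fixed before any of their own values was seen.

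The tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names the 10 genes with the highest mean CPM and the 3 members of each list with the highest mean CPM. It also names the 5 genes with the largest ratio in each direction among those past the threshold with at least 100 reads. For isoforms it names the 2 leading isoforms of the 12 genes with most reads in the isoform list, and the exon with most informative reads in each gene of that list with intermediate inclusion. It further names the 10 microexons with most reads, the 5 genes with the largest isoform share change, the 10 unannotated chains with most reads and the 3 leading antisense and intergenic spliced models. Other genes were named after their values had been seen, and the text says so. Some genes that the rule names are not reported here.

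The alternatives covered model read minimums, mitochondrial genes, ISM reads, Known transcripts alone, scaling by median of ratios or a trimmed mean, read minimums, pseudocounts, depth, list detection limits, exon length limits and leaving out each replicate. Chosen after the data were seen were the ERCC background, a recount of all reads of the strand over a gene's own models, isoform usage without single-exon unannotated models, Fisher's exact test per exon, and the share of exons with intermediate inclusion. The planned test of unannotated splicing against SIRV reads was not run. SIRV sequences were not analysed here, so the share of unannotated splicing was set against no spliced control. ERCC sequences, which are unspliced, were used instead to look for wrongly spliced and antisense reads. edgeR, with both libraries as 1 group, gave a coefficient of variation only.

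The tests were tested on simulated data in which reads varied by counting error alone. The false calls below therefore do not cover spread beyond counting error, which the real libraries showed. In simulated gene counts, 39.6% of 192 genes changed 2-fold and 79.9% of 189 genes changed 4-fold were recovered, with 1 false call among 10825 genes and 2 among 10850. In simulated isoform counts, 77.4% of 195 genes with 20 points moved from the leading isoform were recovered, with 11 false calls among 2058 genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.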

Results

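The series profiled the left cerebral cortex of male B6CASTF1/J mice at 14 days of age by long-read RNA sequencing, with 2 libraries of 1 group. B6CASTF1/J is a first-generation cross between C57BL/6J and the wild-derived CAST/EiJ strain. The libraries held 782521 reads for replicate 1 and 935052 for replicate 2, spread over 116776 and 130406 transcript models. ERCC spike-in reads made up 0.955% and 1.16% of them. Annotated mouse genes with a read numbered 16303 and 16694. With 1 group, the labels give no comparison of conditions, and the values describe the cortical transcriptome and how far the replicates differed.

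Genes of tubulins and calmodulin were among the 10 with the highest mean CPM. The tubulin genes Tuba1a on chromosome 15 (98949837 to 98953703) and Tubb2a on chromosome 13 (34074274 to 34078007) stood at 5703 ± 1190 and 5366 ± 650.3 CPM (mean ± SD, n = 2). Apoe, the main lipid carrier secreted by astrocytes, stood at 4423 ± 574 CPM, and Cpe, which processes neuropeptide precursors, at 3788 ± 156 CPM. Also among the 10 highest genes were Ubb (3698 ± 205 CPM), the calmodulin gene Calm2 (3183 ± 226 CPM), Ndrg4 (2774 ± 440.1 CPM), Nrgn (2733 ± 1120 CPM) and Hspa8 (2506 ± 206 CPM). Reads of near-identical copies, such as those of Tubb2a and of Ubb, can be split by the counting, so their levels are uncertain. Genes of the mitochondrial genome together held 0.0298% and 0.0440% of mouse reads. Protein-coding genes took 88.9% of mouse reads in replicate 1 and 88.3% in replicate 2.

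Most mouse reads matched an annotated transcript. Known transcripts held 65.3% ± 0.996 of reads (SD, n = 2), incomplete splice matches 9.91% ± 0.297 and antisense models 8.09% ± 0.216. NIC chains held 6.26% ± 0.147, genomic models 5.61% ± 0.571, NNC chains 4.12% ± 0.00569 and intergenic models 0.757% ± 0.0532. Among reads of Known transcripts, 95.8% ± 0.215 fell on protein-coding transcripts and 1.26% ± 0.123 on retained-intron transcripts. Of the incomplete splice matches, 69.9% ± 1.16 held the downstream part of the annotated chain, 7.61% ± 0.325 the upstream part, and 20.6% ± 1.04 were single exons. The median Known spliced read came from a model of 2357 bases with 8 exons in replicate 1 and of 2298 bases with 7 exons in replicate 2. Models with a single read were 62.0% and 61.3% of all models and held 9.25% and 8.54% of reads.

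**Figure D1:**
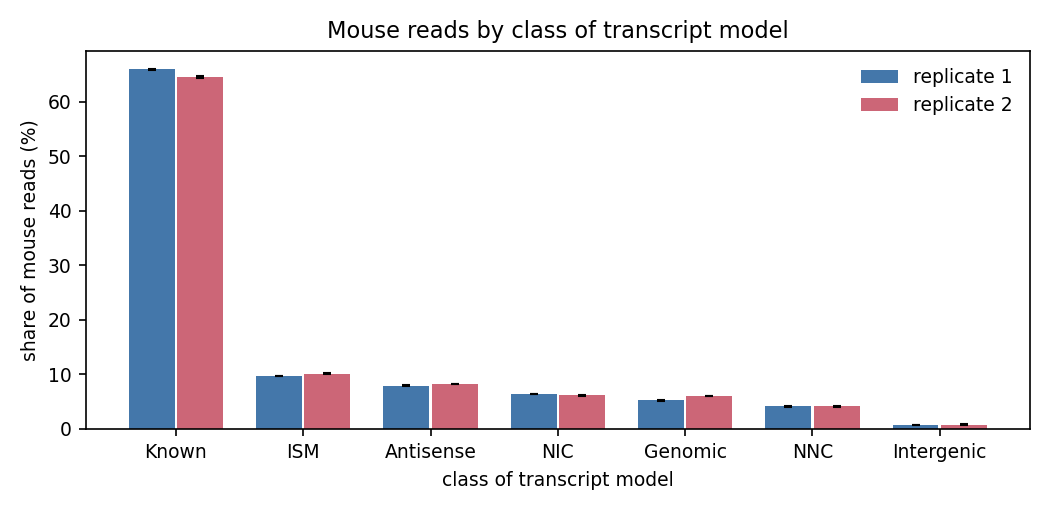
Share of mouse reads (percent) in each class of transcript model, for replicate 1 and replicate 2, with black bars for 95% Wilson intervals. Known transcripts hold 66.0% and 64.6% of reads, and antisense models hold 7.94% and 8.24%.

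Spliced chains absent from the annotation were a regular part of these libraries. NIC and NNC chains held 12.8% of spliced reads in replicate 1 (81162 of 632140, 95% Wilson interval 12.8% to 12.9%) and 12.8% in replicate 2 (94937 of 740525, 12.7% to 12.9%). Over all mouse reads their share was 10.5% and 10.3%. When models with fewer than 5 reads were left out, the share of spliced reads was 6.52% and the share of all reads 5.42%. ERCC sequences are unspliced. Of the ERCC reads, 0 of 7473 in replicate 1 (95% Wilson interval up to 0.0514%) and 2 of 10830 in replicate 2 (up to 0.0673%) were assigned to spliced models. On the antisense strand lay 0.95% (71 reads, 0.754% to 1.20%) and 1.02% (111 reads, 0.852% to 1.23%) of ERCC reads. Counted by the class of the gene, antisense reads were 43.9% of 140162 and 44.0% of 180448 single-exon mouse reads, but 0.309% and 0.313% of spliced mouse reads. Set against all mouse reads, the single-exon antisense reads were 7.94% and 8.59%.

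Replicate 1 held relatively more RNA of striatal marker genes and of myelin genes, and replicate 2 held more of Ttr, Nrgn and haemoglobin. Of 18366 genes with a read, 14631 had one in both libraries, and CPM correlated across genes with Pearson's r of 0.936 and Spearman's rho of 0.934. Genes are not independent replicates, so no p is given. By Fisher's exact test, 236 of 11203 tested genes differed between the libraries, 123 higher in replicate 2 and 113 higher in replicate 1, and 84 of them by over 2-fold. At an unadjusted p under 0.05 there were 1254. The chi-square over all tested genes was 23659 on 11202 degrees of freedom, so the replicates differed beyond counting error and are not 1 library deposited again. The coefficient of variation estimated by edgeR was 0.129. The test compares these libraries, not conditions.

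Penk, which encodes the precursor of enkephalin peptides, lies on chromosome 4 (4133531 to 4138819) and had 166 reads in replicate 1 and 36 in replicate 2. Its log2 ratio of replicate 2 over replicate 1 was -2.44 (95% interval -2.96 to -1.93; Fisher's exact test, adjusted p = 1.09e-23). Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32 on chromosome 11 (98348404 to 98357796), had 407 and 146 reads and a log2 ratio of -1.73. Meis2, a homeobox transcription factor gene on chromosome 2 (115863064 to 116065839), had 74 and 30 reads and a log2 ratio of -1.54 (-2.15 to -0.93). With reads of Known transcripts alone Meis2 did not pass the test, at -0.88. In the other direction, Ttr, the thyroid hormone carrier of the choroid plexus on chromosome 18 (20665280 to 20674321), had 28 and 228 reads and a log2 ratio of 2.75 (2.19 to 3.31; Fisher's exact test, adjusted p = 7.73e-30). Gm21887 on chromosome X (170009659 to 170019281) had 22 and 78 reads (log2 ratio 1.55), and Rps27a, a ribosomal protein gene on chromosome 11 (29545846 to 29548109), had 37 and 109 (log2 ratio 1.29). Ribosomal protein genes have many processed copies, so the count of Rps27a is uncertain.

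For 3 of the remaining 4 genes with the largest ratios, the difference was much smaller when all overlapping reads of the strand were counted, so their ratios are uncertain. Gm13872, an antisense gene on chromosome 2 (102737907 to 102746760), had 1714 reads in replicate 1 and 0 in replicate 2, at least 681-fold lower against a floor of 3 counts. All reads of its strand over its own models numbered 1715 and 2289, a log2 ratio of 0.16. In that count it passed the test in the opposite direction (Fisher's exact test, adjusted p = 0.028). Gm49450 on chromosome 15 (98932137 to 98953551) had 3 and 215 reads (5.69, 4.17 to 7.21). It overlaps Tuba1a on the same strand, whose 5072 and 4493 reads fix that count (-0.36), so the assignment of its own reads is uncertain. Ccdc159 on chromosome 9 had 4 and 176 reads (5.04) but 215 and 282 (0.14), and the pseudogene Vcp-rs on chromosome X had 104 and 22 (-2.47) but 119 and 97 (-0.55). Neither Ccdc159 nor Vcp-rs passed the test in that count, which was chosen after the data were seen.

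**Figure D2:**
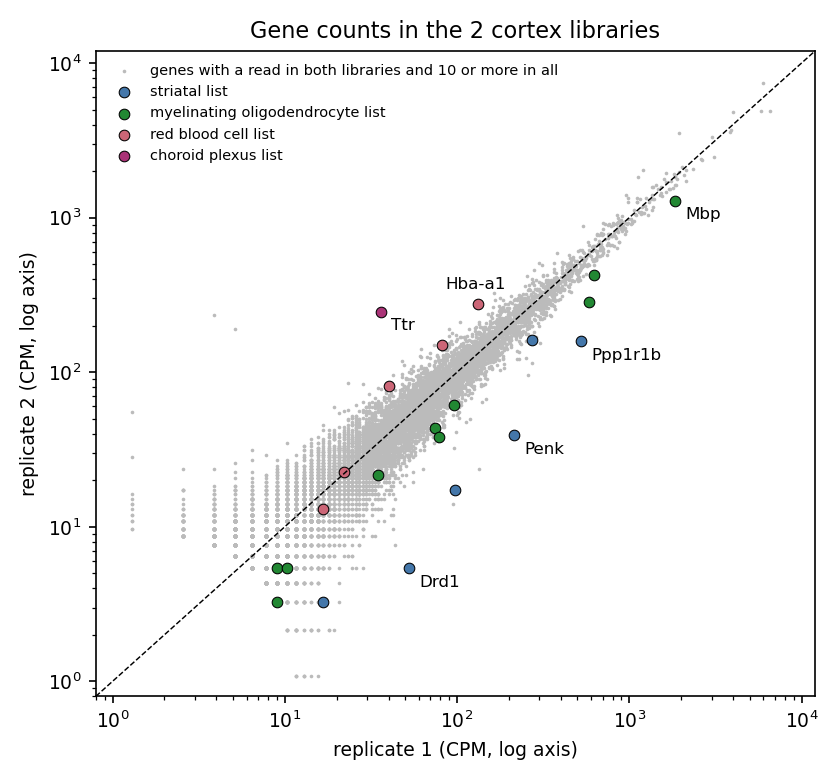
CPM of each gene in replicate 1 (x) and replicate 2 (y), both on log axes, with members of 4 gene lists coloured and the dashed line at equal CPM. Penk (214 and 39.0 CPM) and Drd1 lie below the line, and Ttr (36.1 and 247 CPM) and Hba-a1 (133 and 278 CPM) above it.

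Across the 26 gene lists, 232 of 268 list memberships were detected with at least 3 reads in both libraries. In 9 lists the median ratio lay outside the central 95% of random lists, 4 of them lower and 5 higher in replicate 2. For 26 lists of independent genes 1.3 would be expected. Genes of a list can vary together and some are in several lists, so 9 against 1.3 is no test. All ratios of lists are log2 values of replicate 2 over replicate 1.

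Markers of glutamatergic neurons were abundant. The excitatory neuron list had a median of 121 ± 4.19 CPM, with Nrgn, a postsynaptic calmodulin-binding protein, at 1942 and 3525 CPM. Nrgn was higher in replicate 2 (log2 ratio 0.86, 0.77 to 0.95; Fisher's exact test, adjusted p = 5.43e-83). Slc17a7, the vesicular glutamate transporter, stood at 1342 ± 36.7 CPM and Nrn1 at 228 ± 45.7 CPM. Of the 9 tested genes 1 was higher and 0 lower, with 3 past the threshold adjusted over the list alone, and the list median of 0.11 lay within the random range. With Known transcripts alone that median was -0.11. Among upper layer genes, Lamp5 (163 ± 28.0 CPM), Cux1 (65.8 ± 11.0 CPM) and Cux2 (43.6 ± 17.9 CPM) led, and 0 of 5 passed over all genes or adjusted over the list alone (median 0.35). The deep layer list was lower in replicate 2 (median -0.76, random range -0.57 to 0.52), with 1 of 5 past the test and 2 adjusted over the list alone. Crym had a log2 ratio of -0.90, Bcl11b -1.08 and Fezf2 0.89, of which only Crym passed over all genes. Crym and Bcl11b are also known to be expressed in the striatum. Of 9 tested interneuron genes 0 passed and 1 did so adjusted over the list alone (median 0.09), led by Gad1 (263 ± 57.6 CPM), Npy (81.5 ± 24.0 CPM) and Vip (51.6 ± 12.7 CPM).

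Among glia, myelin genes were the group that differed most. In the myelinating oligodendrocyte list all 10 tested genes were below 0 (median -0.74, random range -0.27 to 0.25), with 4 past the test and 6 adjusted over the list alone. Mbp, a structural protein of compact myelin, had 1423 and 1188 reads (log2 ratio -0.51, -0.63 to -0.40), and Cnp 482 and 393 (-0.55). Ugt8a, named after its value was seen, was also past the test (-1.05). The striatal and deep layer lists lay on the same side, with medians of -2.44 and -0.76. Oligodendrocyte precursor genes had a median of -0.18 within the random range, with 0 of 7 past the test over all genes or adjusted over the list alone. Their leading members were Olig1 (128 ± 3.4 CPM), Olig2 (79.6 ± 20.7 CPM) and Gpr17 (54.7 ± 0.701 CPM). The astrocyte list was slightly higher in replicate 2 (median 0.23, random range -0.21 to 0.17). In it 1 of 10 genes passed, Aldoc at 1221 ± 169.7 CPM (log2 ratio 0.28), and 3 adjusted over the list alone. The gap junction gene Gja1 had 634 ± 80.3 CPM and the glutamate transporter Slc1a3 had 625 ± 54.8 CPM. Microglial genes, among them P2ry12 (85 and 88 reads) and Csf1r (93.2 ± 12.4 CPM), had a median of -0.04, and 0 of 8 passed over all genes or adjusted over the list alone.

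Vessel genes did not stand apart, while meningeal, choroid plexus and blood genes did. Of 7 endothelial genes (median 0.27) and 6 mural genes (median 0.34), 0 passed over all genes or adjusted over the list alone. Cldn5 (337 ± 16.4 CPM), Slc2a1 (117 ± 23.7 CPM) and Slco1a4 (48.2 ± 8.48 CPM) led the endothelial list, and Rgs5 (134 ± 6.70 CPM), Vtn (75.5 ± 6.44 CPM) and Acta2 (26.4 ± 10.0 CPM) the mural list. In the meningeal fibroblast list all 5 tested genes were above 0 (median 0.87, random range -0.48 to 0.53). The fibrillar collagen gene Col3a1 was the 1 gene past the test over all genes and adjusted over the list alone (57 and 139 reads, log2 ratio 1.02), and Col1a1 and Dcn had log2 ratios of 0.11 and 0.67. Ttr was the only gene of the choroid plexus and ependymal list with enough reads to test, and it passed both adjustments, so the list median of 2.75 is that of Ttr. Kl had 2 and 4 reads and Clic6 0 and 5. In the red blood cell list 3 of 5 genes were higher in replicate 2 by either adjustment (median 0.88, random range -0.42 to 0.40, and -0.19 to 0.71 with lists also matched on transcript length). These were Hba-a1 (103 and 257 reads, log2 ratio 1.06), Hbb-bs (63 and 139, 0.88) and Hba-a2 (31 and 75, 1.01). The paired haemoglobin genes are near-identical copies, so the split of reads within each pair is uncertain.

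Striatal markers showed the lowest list median of all. All 7 tested genes were below 0 (median -2.44, random range -0.33 to 0.30), 6 passed over all genes and 7 adjusted over the list alone. Ppp1r1b and Penk had log2 ratios of -1.73 and -2.44. Named after their values were seen, Rgs9 had 75 and 16 reads (-2.45), the dopamine receptor genes Drd1 41 and 5 (-3.17) and Drd2 13 and 0, and Tac1 13 and 3 (-2.20, -3.90 to -0.51, not past the test over all genes). Drd2 was at least 5.17-fold lower against a floor of 3 counts, and with Drd2 at that bound the list median was -2.37. The other regional lists were sparse and lay within the random range. The hippocampal list had 1 tested gene (Fibcd1, median 0.42; C1ql2 and Spink8 followed), the olfactory bulb list 3 (Cdhr1, Th and Doc2g, median -0.25) and the thalamic list 3 (Calb2, Slc17a6 and Prkcd, median -0.25). In none of these 3 lists did a gene pass over all genes or adjusted over the list alone.

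**Figure D3:**
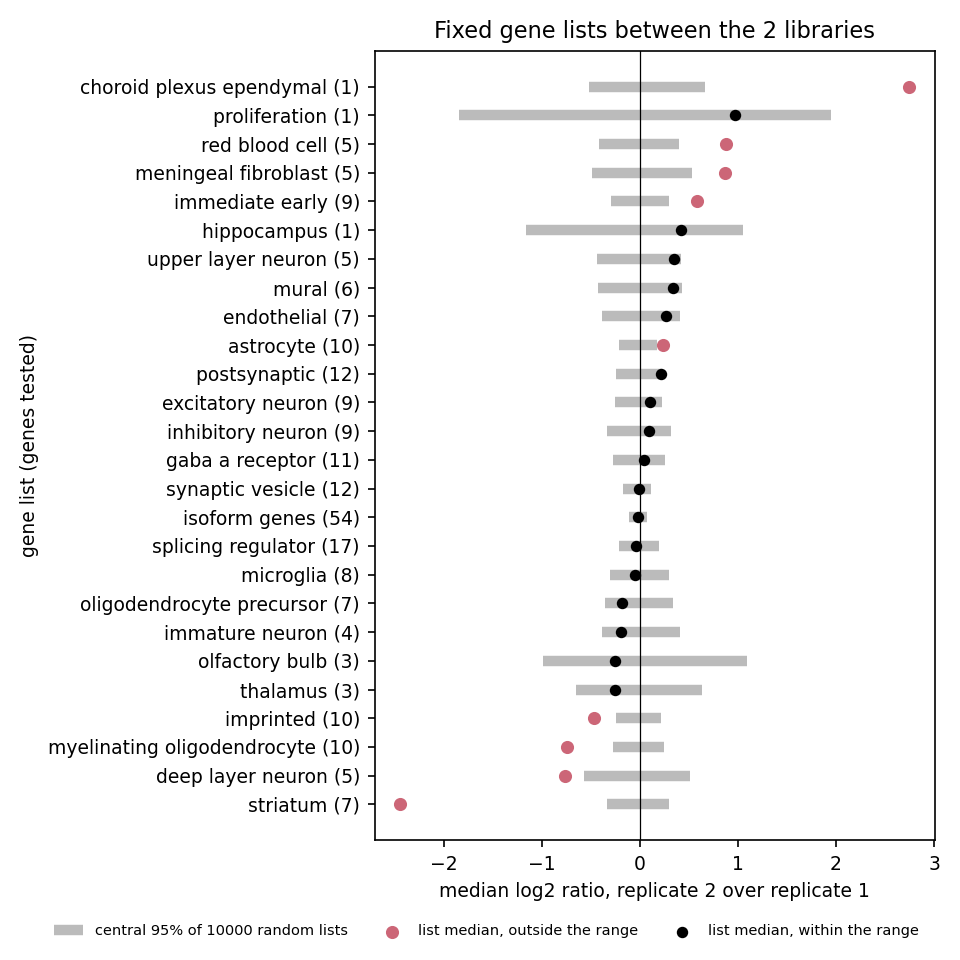
Median log2 ratio of replicate 2 over replicate 1 (x) for each gene list (y, genes tested in brackets), as points over grey bars for the central 95% of 10000 random lists matched on expression. The striatal list lies lowest at -2.44 and the choroid plexus list, with 1 gene, highest at 2.75.

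Immature neuron genes were led by Stmn2 (644 ± 43.4 CPM), Tubb2b (72.9 ± 0.935 CPM) and Sox4 (64.4 ± 23.8 CPM), with 0 of 4 past the test, 1 adjusted over the list alone and a median of -0.20. Proliferation genes were near the detection limit: Ccnb1 had 4 and 10 reads, Birc5 3 and 4, and Cdk1 4 and 2. Ccnb1 alone could be tested in that list (median 0.97), and 0 passed over all genes or adjusted over the list alone. All 9 tested immediate early genes, which neurons transcribe after activity, were above 0 (median 0.59, random range -0.30 to 0.29). Of these 1 passed and 2 did so adjusted over the list alone. Junb (158 ± 31.2 CPM), Egr4 (105 and 152 reads) and Egr1 (85.3 ± 29.4 CPM) led, and Arc, named after its value was seen, was the gene past the test (38 and 103 reads, log2 ratio 1.17).

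Synaptic vesicle genes were at high and similar levels in both libraries. The synaptic vesicle list had a median of 719 ± 3.13 CPM, led by Syp (1840 ± 5.39 CPM), Snap25 (1284 ± 32.9 CPM) and Vamp2 (1179.6 ± 109.9 CPM), and its median ratio was -0.00. Of 12 genes 1 was higher in replicate 2, Stx1a (log2 ratio 0.29, named after its value was seen), and 2 adjusted over the list alone. The postsynaptic list (Grin1 at 481 ± 17.7 CPM, Gria2 at 336 ± 22.6 CPM and Gria1 at 141 ± 6.58 CPM) had 1 of 12 genes past either adjustment, Dlg4 (0.88, named after its value was seen), and a median of 0.22 (random range -0.24 to 0.23), with 10 genes above 0. GABA-A receptor genes had a median of 0.04, and 0 of 11 passed by either adjustment. The imprinted list was lower in replicate 2 (median -0.47, random range -0.24 to 0.22), with 2 of 10 genes past the test and 3 adjusted over the list alone. Ndn had 463 and 379 reads (log2 ratio -0.54), while Snrpn (1851 ± 4.12 CPM, 0.00) and the non-coding Meg3 (468 ± 20.1 CPM, 0.09) did not pass. The other imprinted gene past the test was Nnat (-0.82, named after its value was seen). Splicing regulators, led by Celf4 (538 ± 56.8 CPM), Rbfox3 (362 ± 49.1 CPM) and Khdrbs3 (345 ± 26.2 CPM), had a median of -0.03, with 0 of 17 past either adjustment. In the list of 54 genes with known isoforms (Snrpn, Mbp and Gnas the highest), 1 was higher and 2 lower, with 4 adjusted over the list alone and a median of -0.02.

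Most expressed genes used 1 main isoform. Among 2631 genes with at least 50 reads in each library, the leading isoform held a median of 88.2% of reads, and 762 genes had at least 2 isoforms at 10% or more in both libraries. That number was 1083 with a minor share of 5%, 1008 of 2986 with incomplete splice matches, 483 of 2213 with Known transcripts alone and 369 with a minor share of 20%. With 100 reads per gene it was 345 of 1238 genes (27.9%), against 29.0% of the 2631. The leading isoform was a Known transcript in 2489 genes, a NIC chain in 111 and an NNC chain in 31, and it was the same in both libraries in 2551 genes (97.0%).

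In the genes of the isoform list with most reads, the leading isoforms held similar shares in both libraries. The SD was largest for Grin1-201, at 5.31 points. These shares are of the gene's reads in Known, NIC and NNC models. Cdc42, a small GTPase whose alternative last exons give a brain form and a widely expressed form, had 49.2% ± 1.15 (SD, n = 2) of reads in Cdc42-202 and 46.1% ± 0.978 in Cdc42-201. Snap25, which joins vesicles to the presynaptic membrane, had 74.7% ± 0.197 in Snap25-201 and 23.5% ± 0.188 in Snap25-202. Mbp had 50.9% ± 2.46 in Mbp-211 and 18.3% ± 2.18 in Mbp-212. Grin1, the obligatory NMDA receptor subunit, had 37.2% ± 5.31 in Grin1-201 and 18.7% ± 1.45 in Grin1-205. The pyruvate kinase gene Pkm had 83.1% ± 1.5 in Pkm-202 and 14.1% ± 1.59 in Pkm-201. Single isoforms dominated Gnas (Gnas-208, 95.2% ± 0.608, then Gnas-221 at 1.66% ± 0.729), App (App-201, 90.9% ± 0.345, then App-206 at 2.37% ± 1.30) and Snrpn (Snrpn-201, 86.9% ± 1.95, then an NNC chain at 3.43% ± 0.703). For Camk2b the shares were 71.8% ± 1.57 in Camk2b-209 and 5.01% ± 1.20 in a NIC chain. Unannotated chains led in Apbb1 (a NIC chain of 14 exons at 60.6% ± 1.56, then another of 13 exons at 8.62% ± 0.913) and in Tpm3 (a NIC chain of 8 exons at 69.3% ± 0.679, then Tpm3-201 at 15.3% ± 2.23).

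Differences in isoform usage between the libraries lay mostly in single-exon models. Of 1936 genes tested, 158 passed the chi-square test, and in 94 of these the largest change was in single-exon models. When single-exon unannotated models were left out, 8 of 1802 genes passed. With incomplete splice matches left out 18 of 1346 passed, 7 of them among the 158, and with Known transcripts alone 3 of 757 did. The largest share changes were in Stmn4 (single-exon models at 0 of 55 and 81 of 157 reads), Epb41l1 (0 of 57 and 71 of 140), Ncs1 (0 of 83 and 69 of 152) and Tmem151a (62 of 138 and 0 of 106). In Plppr2 the annotated Plppr2-201 held 26.3% and 72.1% of reads (chi-square test, adjusted p = 6.00e-18). Plppr2 lies beside Ccdc159, whose ratio was uncertain. Among the 3 genes past the test with Known transcripts alone were Rsrp1 and Cox4i1, named after their values were seen, with changes of 11.7 and -9.24 points in 1 isoform.

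Inclusion of cassette exons correlated closely between the libraries. Of 7527 internal exons with enough reads and a read that skipped them, 1593 in 1181 genes had a mean inclusion between 5% and 95%. Inclusion of these 1593 exons correlated across exons with r of 0.973. Their number was 2702 of 9835 with at least 10 informative reads, 631 of 4225 with at least 50, and 471 of 905 with Known transcripts alone. No exon differed between the libraries by Fisher's exact test after adjustment (0 exons, 77 at an unadjusted p under 0.05), a test added after the data were seen.

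The 78 bp exon of Mbp, found in isoforms of early myelin (chromosome 18, 82561778 to 82561855), was included in 24.7% ± 0.427 of reads (SD, n = 2). The 63 bp exon of Grin1 in the amino-terminal domain (chromosome 2, 25311343 to 25311405) was included at 19.3% ± 2.55. The neuronal inserts of the clathrin light chains were included at 82.9% ± 7.80 for the 36 bp exon of Clta and 86.1% ± 1.20 for the 54 bp exon of Cltb. High inclusion was also seen for the 45 bp exon of Camk2b (94.1% ± 2.56), the 93 bp exon of Bin1 (86.3% ± 1.42), the 24 bp exon of Mef2a (90.7% ± 6.02) and the 21 bp exon of Mef2d (90.3% ± 5.14). Intermediate values came from the 183 bp exon of Ank2 (59.1% ± 0.172), the 36 bp exon of Nrcam (57.7% ± 8.33), the 57 bp exon of App (62.5% ± 17.7), the 74 bp exon of Dclk1 (38.6% ± 0.509), the 114 bp exon of Camk2g (36.8% ± 2.68), the 89 bp exon of Camk2d (32.9% ± 2.16) and the 190 bp exon of Map4 (34.7% ± 3.42). Low values came from the 87 bp amino-terminal insert of Mapt (7.44% ± 3.31), the 79 bp exon of Tpm3 (7.85% ± 0.763), the 801 bp exon of Ncam1 (19.4% ± 5.59), the 115 bp exon of Gria2 (7.17% ± 0.389), the 93 bp exon of Map2 (7.81% ± 11.0) and the 40 bp exon of Apbb1 (24.7% ± 6.07). Unannotated exons were seen in Gphn (39 bp, 16.9% ± 2.05), Gnas (2068 bp, 25.8% ± 2.14) and Snrpn (312 bp, 6.32% ± 4.52). Each percentage covers only reads with the same neighbouring splice sites, so it is not the share of all transcripts of a gene that hold the exon. For App these were 42 and 44 reads, while 687 and 759 of its reads lay in Known, NIC and NNC models. For Gria2 they were 94 and 87 reads. Wide gaps between the libraries were seen in the 37 bp exon of Dnm1 (3 of 20 and 11 of 22 reads) and the exon of App (21 of 42 and 33 of 44). Neither passed the test (for Dnm1, Fisher's exact test, adjusted p = 0.999). With incomplete splice matches left out, inclusion was 29.6% for Ncam1, 31.3% for Map2, 25.8% for Nrcam, 80.6% for Ank2 and 12.5% for Dnm1. With Known transcripts alone it was 26.8% for Tpm3, 79.0% for Dclk1, 66.3% for Bin1 and 50% for Map4.

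**Figure D4:**
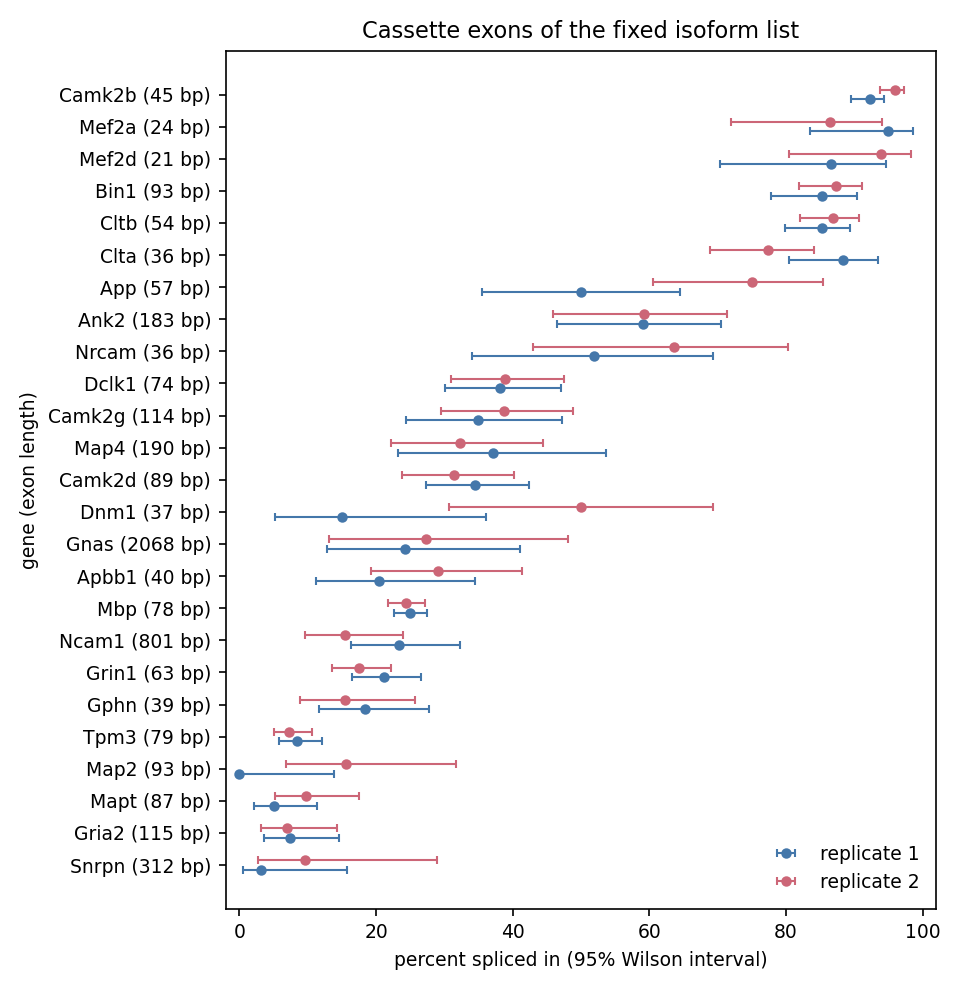
Percent spliced in (x, with 95% Wilson intervals) of the cassette exon with most informative reads in genes of the isoform list (y, exon length in brackets), for replicate 1 and replicate 2. Camk2b lies highest at 94.1% on average and Snrpn lowest at 6.32%.

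Microexons with many reads ranged from near-constant inclusion to near-constant skipping. Of the 10 with most reads, the 24 bp exon of Aplp1 was included in 1545 of 1546 and 1944 of 1944 reads and the 22 bp exon of Palm in 373 of 374 and 437 of 437. Intermediate inclusion was found for the 27 bp exon of the phosphatase gene Ptpra (56.0% ± 4.86, SD, n = 2) and the 18 bp exon of Nckap1 (57.4% ± 1.17), a gene of actin regulation. Kif5c, a kinesin gene, included a 27 bp exon in 0 of 271 and 1 of 295 reads. The remaining 5, in Pak1, Slc30a9, Schip1, Myl6 and Rell2, were included at 1.89%, 0.216%, 0.431%, 0.756% and 0.220%. Medians were taken over 142 microexons and 7067 longer exons, of which 43 and 2092 were unannotated. Exons that no read skipped were left out. The median inclusion of microexons was 61.5% in replicate 1 and 60.1% in replicate 2, against 87.5% and 86.4% for longer exons. These differences did not pass the permutation test (p = 0.138 and 0.132). They passed with a length limit of 3 to 51 bp, and in replicate 2 with at least 10 informative reads. With Known transcripts alone the medians differed by 0.778 and 5.78 points in the opposite direction, not past the test. Inclusion between 5% and 95% was more frequent among microexons (56 of 142, 39.4%) than among longer exons (1481 of 7067, 21%; Fisher's exact test, p = 7.30e-07), a test added after the data were seen.

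Some genes were represented almost wholly by a spliced chain outside the annotation. Of 72001 unannotated chains, 11889 (16.5%) were found in both libraries and held 60.9% of the reads of such chains, and 698 in 578 genes had at least 10 reads in both. In Nrgn an NNC chain of 3 exons (chromosome 9, introns from 37545349 to 37552536), with 1 splice site 17 bases from the nearest annotated one, held 94.8% ± 0.654 of the gene's reads (SD, n = 2). NIC chains held 95% ± 1.32 in Oaz1 and 91.1% ± 1.13 in Oaz2, the antizyme genes that limit polyamine synthesis and are known for programmed frameshifting. Both chains held 0 unannotated introns, so only their combination of introns was outside the annotation. Sept7, a septin gene, had 86.7% ± 2.26 in a NIC chain of 13 exons. NNC chains with 1 unannotated splice site held 89.1% ± 0.877 in Pitpna, 85.2% ± 4.43 in Uchl1, a neuronal deubiquitinase gene, and 82.3% ± 0.489 in Dctn2. These sites lay 4, 9 and 10 bases from annotated ones. In Aplp2, Apbb1 and Ctbp1, NIC chains held 63.1% ± 3.71, 56.3% ± 1.77 and 53.7% ± 0.863 of the genes' reads, also with 0 unannotated introns. Shares in this paragraph are of all reads of the gene, so that of Apbb1 is below the 60.6% given for its leading isoform.

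Outside annotated genes, few spliced models were shared by the libraries, 156 antisense and 18 intergenic chains. The antisense model with most reads lay opposite Slitrk5, a neuronal adhesion gene, on chromosome 14 (111675097 to 111681887, 2 exons, 171 and 193 reads). The next lay opposite Prpf38b on chromosome 3 (108903147 to 108906983, 33 and 39 reads) and opposite Crebbp and Gm37186 on chromosome 16 (4128444 to 4213997, 6 exons, 34 and 34 reads). Spliced intergenic models had few reads, 10 and 6 on chromosome 1 (131851862 to 131852163), 2 and 6 on chromosome 14 (43118790 to 43120241) and 2 and 5 on chromosome 5 (104571709 to 104585120). Single-exon antisense loci numbered 23050, of which 8032 were found in both libraries, and 87 with at least 100 reads held 34.7% of their reads. The locus with most reads lay opposite Gm26917 on chromosome 17 (39843013 to 39846245, 5181 and 7171 reads). It alone held 9.18% of the reads of these loci, while Gm26917 itself had 6 and 20 reads. Another locus with many reads lay opposite Snhg11 (2278 and 2773 reads, against 131 and 145 for the gene). Both loci were named after their values were seen.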

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

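The recount of all reads of the strand over a gene's own models and the isoform test without single-exon unannotated models were chosen only after the results were seen. Over 92 results, 304 alternatives were computed. Of these, 252 kept their direction and side of the threshold or stayed within the tolerance for values with no test. Another 44 moved beyond that tolerance, 3 no longer passed the test, 3 newly passed it and 2 turned direction. The 252 include alternatives that could not have moved, given below, so their number is no measure of stability. The 236 genes that differed between the libraries became 189 to 256 under the other scalings and read minimums (with median of ratios factors 152 of 253 were higher in replicate 2, against 123 of 236), 166 with Known transcripts alone (139 of them among the 236) and 229 in the recount. The lists outside the random range were the same 9 with Known transcripts alone, and 46 of 51 list medians kept their place. The 5 that moved changed sign, in the excitatory neuron, synaptic vesicle, splicing regulator and isoform lists, whose medians lay within the random range. Median of ratios factors shift every ratio alike and so cannot move a list against random lists. Those alternatives, counted among the 51 and the 304, therefore show nothing about the place of a list.

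With models of 5 or more reads, Known transcripts held 76.3% of reads, NIC and NNC chains 5.42%, antisense models 6.62% and unannotated chains 6.52% of spliced reads. With incomplete splice matches left out, unannotated chains held 14.2% of spliced reads, since fewer reads were counted. The correlation across genes was 0.931 after thinning to the smaller depth, 0.941 with 10 or more reads, 0.805 with a pseudocount of 0.1 CPM and 0.976 with 10 CPM. In the recount, Gm13872 had a log2 ratio of 0.16 and Gm49450 of -0.36. The value for Gm49450 is fixed by the reads of Tuba1a in that count and says nothing about Gm49450. Isoform usage differed in 18 genes without incomplete splice matches, 3 with Known transcripts alone and 8 without single-exon unannotated models. Genes with at least 2 isoforms numbered 1083 at a minor share of 5%, 1008 of 2986 with incomplete splice matches, 483 of 2213 with Known transcripts alone, 369 at a minor share of 20% and 345 of 1238 at 100 reads (27.9%, against 29.0% of 2631). The leading share was 78.0% with incomplete splice matches, 98.8% with Known transcripts alone and 90.9% at 100 reads. Exons of intermediate inclusion numbered 2702 of 9835 at 10 informative reads, 631 of 4225 at 50 and 471 of 905 with Known transcripts alone, against 1593 of 7527. The microexon difference was -58.8 and -57.6 points with a limit of 51 bp and -36.3 points in replicate 2 with 10 informative reads, all past the permutation test. With Known transcripts alone it was 0.778 and 5.78 points, over 26 microexons. The cause was not tested for these values.

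Leaving out each replicate gave ranges of 64.6% to 66.0% for Known transcripts, 10.3% to 10.5% for NIC and NNC chains, 7.94% to 8.24% for antisense models, 239 to 245 for detected list members, 898 to 1110 for genes with at least 2 isoforms, 87.1% to 88.3% for the leading share and 1783 to 1934 for exons. For the 38 named exons, 40 of 55 alternatives by model class stayed within 1 SD and 15 did not. Leaving out 1 of 2 replicates always moves a mean by less than 1 SD, so those 76 alternatives, also counted among the 304, show nothing about stability. No paired analysis was possible because the labels give 1 group. The planned test against SIRV reads was not run. Depth limits the test of genes, which recovered 39.6% of simulated 2-fold changes, so genes not past it may still differ by that much.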

Other observations

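The gene families, the split at 1200 bases, the finer match on length, the sum without Enpp2 and Igfbp2 and the tests of scaling, of length as the whole cause and of the ERCC strand rate were chosen only after the results were seen. The labels give 1 group, so no biological explanation was tested.

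Nuclear genes of the mitochondrial respiratory chain with transcripts under 1200 bases were mostly higher in replicate 2, and the longer ones were not. Of 77 tested genes of all lengths, 19 passed the test as higher and 1 as lower. Cox4i1, a subunit of cytochrome c oxidase, had 875 and 1700 reads (log2 ratio 0.70; Fisher's exact test, adjusted p = 5.47e-30), Cox8a 416 and 815 (0.72), Uqcrq 218 and 421 (0.69) and the complex I gene Ndufb7 81 and 195 (1.01). The lower gene was Atp5a1, a subunit of ATP synthase (1068 and 1082 reads, log2 ratio -0.24). Genes of cytoplasmic ribosomal proteins lay on the same side, with 11 of 77 higher and 0 lower, among them Rpl41 (241 and 458 reads, 0.67) and Rps28 (48 and 131, 1.19). The family medians were 0.41 and 0.38 over the 75 and 77 genes with a length, and the other scalings shift all ratios by only 0.03 and 0.01. Ribosomal protein genes have many processed copies, so their single counts are uncertain.

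Striatal markers were lower in replicate 2, and Ttr and meningeal genes were higher, for which a candidate explanation is that the samples held different amounts of neighbouring tissue. A second striatal list that shares no gene with the first had a median log2 ratio of -1.02 (matched random range -0.37 to 0.27), with all 9 tested genes below 0 and 5 past the test, among them Gng7 (288 and 169 CPM), Pde1b (178 and 104 CPM) and Adcy5 (103 and 50.9 CPM). With median of ratios factors the first striatal list had a median of -2.41, but that test of scaling is void, since 1 factor moves every gene alike. Summed reads of a second choroid plexus list had a log2 ratio of 0.60 (0.38 to 0.81), with 1 of 3 tested genes past the test, but most came from Enpp2 (193 and 335 reads) and Igfbp2 (74 and 128), which other cells also express, against 5 and 27 reads for the other 9 genes. A second meningeal list had a median of 0.54 (-0.46 to 0.45) over the 9 genes with a length, and of all 11 tested 0 passed the test and 3 were below 0. The values of the 3 second lists are those that the tissue explanation predicts, by tests set before they were seen, but it remains a hypothesis, and for the striatum 6 of the 8 genes of the first list had at least 3 reads in both libraries and cortical neurons express some of them, such as Penk and Ppp1r1b.

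The respiratory chain and ribosomal families have short transcripts, with medians of 763 and 775 bases against 2766 bases for tested genes, so a bias by transcript length between the libraries may contribute. Outside the families, the shortest of 10 length classes of genes had a median log2 ratio of 0.18, as such a bias would give. The respiratory median of 0.41 lay at percentile 100 of random lists matched on expression and length (0.09 to 0.28). It also lay above a finer match on length (0.00 to 0.25). The family was chosen after its values were seen, so these matches cannot decide whether length is the whole cause. Within the family, however, the 55 genes under 1200 bases had a median of 0.49 with 52 above 0, and the 20 longer genes -0.05 with 9 above 0, while the 13 longer ribosomal protein genes had 0.33. What else differs between the libraries for these families was not tested.

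Single-exon reads assigned to antisense genes, counted by the class of the gene, were 7.94% and 8.59% of mouse reads. Reads placed on the wrong strand at the rate of the ERCC spike-ins are argued against as the whole cause, since the upper bounds of that rate were 1.20% and 1.23%. T-rich stretches of the sense transcript, searched just beyond the antisense 3' ends, gave 23.8 times the random share (65.9% against 2.77%). Polyadenylation signals on the antisense strand, searched before these ends, gave 2.55 times (7.55% against 2.96%). T-rich sense bases are A-rich on the antisense strand, so the first test could not tell priming on the sense transcript from priming on an antisense one. Both tests are void, because only 2027 of 26669 ends (7.60%) could be searched. Priming within the sense transcript and antisense transcription therefore cannot be told apart here.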
